A study of Arabidopsis thaliana with 12 samples.

How the data were processed

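Total RNA of Arabidopsis thaliana (ecotype Columbia 0) was measured on 12 expression arrays with 1 value per spot, 6 titled wild type and 6 titled stn7 stn8 double mutant. STN7 and STN8 are the thylakoid protein kinases that phosphorylate the light-harvesting antenna and the core of photosystem II. Groups and replicate numbers were taken from the sample titles. The source field of the labels names wild type for all 12 samples, so the grouping rests on the titles alone. Organ, age, light regime, array type and scanner are not given in the sources used here, and nothing in the labels says whether replicates were separate plants or repeat arrays of 1 extract. The p-values therefore measure only the spread between these arrays, which may be technical.

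The deposited values are intensities on a linear scale, never below 0, for 3439 rows. How the authors scaled them and subtracted background is not given in the sources used here. Column totals lay between 3586 and 3682 in every array, while the medians differed. Per array, 145 to 192 rows were listed at exactly 0 and 0 to 2 rows were empty. Mutant replicates 4 and 5 held the same values, with a largest difference of 4.0e-10, and were counted as 1 sample. All comparisons thus set 6 wild-type arrays against 5 distinct mutant arrays, where the plan had been 6 against 6. The table has no detection flags and no marked control spots, so every row with enough values was tested, and the number of arrays limits the precision.

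Zeros were treated as missing, and the other intensities were transformed to log2. By a rule fixed before the data were examined, quantile normalization was applied because the array medians differed by more than 0.1 on the log2 scale. A row needed 4 measured values in each group. This left 3229 rows, while 210 were not tested, of which 76 were at 0 in all arrays. Fold changes were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the tested rows, with a threshold of 0.05. All adjusted p-values are limma's unless another test is named. Measures of a whole array were compared with exact two-sided permutation tests over the 462 splits of 11 arrays into 6 and 5.

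Gene names came from the platform annotation. It named 1 gene for 692 rows, several for 870 and none for 1877. Of the 692, 690 matched the TAIR10.1 gene table, and they stood for 689 different genes. Only rows with 1 gene are named in the text, and 645 of them were tested. A single name does not exclude hybridisation of near-identical copies, as among the LHCB1 genes. The sources name no genome build, so no coordinates are given.

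By the rule fixed beforehand, the text names the 10 rows with 1 gene of largest fold change in each direction that kept an adjusted p under 0.05, with the same sign, when each array was left out in turn. It also names the 3 members with the smallest p of each gene list. The 23 lists of chloroplast and related genes, written before the data were examined, were tested with camera at its preset correlation of 0.01 where 3 or more members were measured, against all other rows with a gene name. Members beyond these rules are named only to complete a list. A further 5 lists were written after the names on the array were seen, before any fold change of a named gene was seen. Alternatives changed the scaling between arrays, the handling of dim rows and zeros, the variance model, array weights, a block for the replicate number, the threshold and the gene set test, and left out each array in turn. Further alternatives, chosen after seeing the data, counted the identical arrays as 2 samples, averaged or blocked arrays with consecutive numbers, and left out arrays that stood apart.

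The fit was tested on simulated data for the comparison of mutant and wild type, with 3229 rows, of which 50 were changed at each of 4 sizes. It recovered 20% of the rows changed by 0.3 on the log2 scale, 60% at 0.6, 86% at 1 and 98% at 2. There were 6 false calls, or 4.35% of the calls. The simulated noise was independent between arrays and rows, and far fewer rows were changed than were called in the real data. Wild-type arrays with consecutive numbers resembled each other, so these rates need not hold for the real arrays.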

Results

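The data set holds 12 arrays of total RNA from Arabidopsis, 6 of wild-type Columbia 0 and 6 of the stn7 stn8 double mutant, which lacks a pair of thylakoid protein kinases. Because mutant replicates 4 and 5 were identical, 5 distinct mutant arrays entered the comparison. Within a group, normalized log2 intensities correlated with r from 0.920 to 0.983 across rows for wild type (15 pairs) and from 0.916 to 0.976 for the mutant (10 pairs). Between groups r lay between 0.869 and 0.917 (30 pairs). Rows are not independent replicates, and these r describe the arrays only. No row with 1 gene name stood for STN7 (AT1G68830) or STN8 (AT5G01920), so the transcripts of both targeted genes are not analysed here and the genotype in the titles could not be checked from them.

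As deposited, the arrays of the 2 groups differed in scale. The median log2 intensity was -1.503 ± 0.13 (SD, n = 6) in wild type and -0.96 ± 0.024 (n = 5) in the mutant, a difference of 0.54 (exact permutation p = 0.00216, the smallest that 462 splits allow; 0.00303 after Benjamini-Hochberg adjustment over 7 array measures). The brightest 1% of rows held 37.4% ± 1.48 of the summed intensity in wild type and 27.7% ± 0.714 in the mutant (n = 6 and 5, exact permutation p = 0.00216). These exact p-values hold only if every array is a separate sample. Wild-type medians lay close together within consecutive pairs. They were -1.510 and -1.507 in replicates 1 and 2, and -1.363 and -1.357 in 3 and 4. Replicates 5 and 6 were at -1.648 and -1.633. Averaging such pairs would allow fewer splits and so raise the smallest possible p, but the array measures were not tested in this way. The summed intensities were 3643 ± 25.5 and 3616 ± 29.5 (exact permutation p = 0.139). Quantile normalization removes such a difference, so each fold change below is relative to the distribution of all rows. The median fold change of all tested rows was 0.50 (log2) as deposited and 0.058 after normalization.

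**Figure D1:**
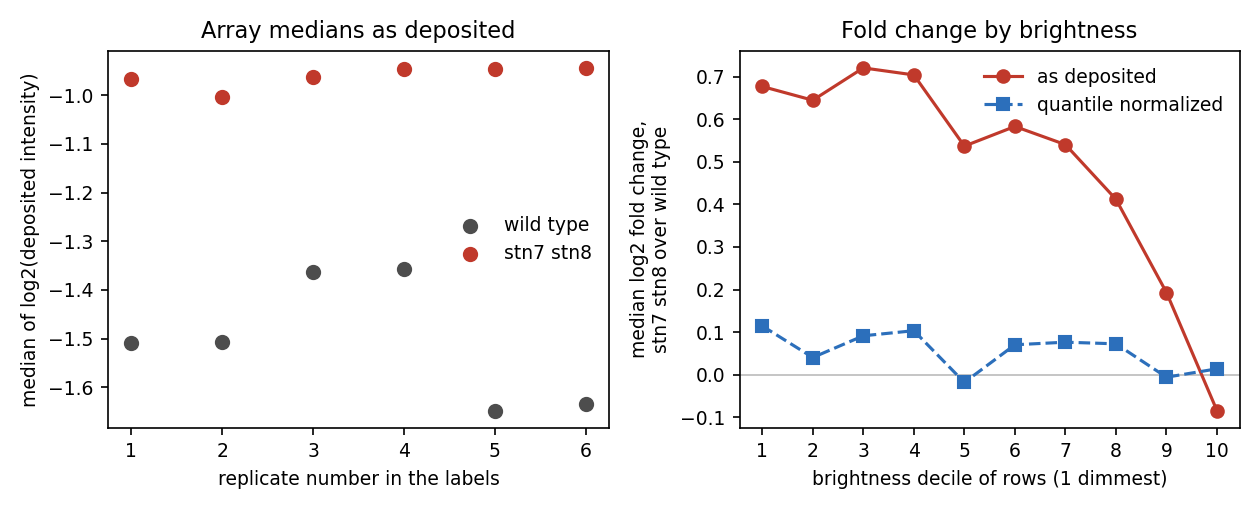
Left, the median log2 intensity of each array as deposited against its replicate number, with wild type in grey and stn7 stn8 in red; mutant replicates 4 and 5 are the same values. Right, the median log2 fold change (mutant over wild type) of rows in 10 brightness classes, as deposited (red) and quantile normalized (blue): as deposited it was 0.68 in the dimmest class and -0.084 in the brightest.

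The comparison of the double mutant with wild type asks which transcripts differ when both kinases are absent. Among genes of photosynthesis, the mutant had 2.13-fold more signal for PSBY, a small membrane protein of photosystem II, while PSB27, an assembly factor of the same complex, was at 0.668 of the wild-type level (n = 6 and 5). PSAN, a lumenal subunit of photosystem I, was at 0.621 and PRK, the phosphoribulokinase of the Calvin cycle, at 0.699 of the wild-type level, but these calls held in only 21 and 26 of 28 alternatives. The other 4 of 8 measured photosynthesis genes, PSBW, LHB1B2, NdhN and SBPASE, did not pass. The catalytic subunit of ferredoxin-thioredoxin reductase (AT2G04700), which passes electrons from photosystem I to plastid thioredoxins, was at 0.458. CHLM, the methyltransferase of magnesium protoporphyrin in chlorophyll synthesis, was 1.43-fold higher.

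Of 3229 rows, limma called 766 higher and 632 lower in the mutant at an adjusted p under 0.05, together 43.3% of those tested. Among rows with 1 gene name the counts were 174 and 104. The values of the groups did not overlap in 932 rows, or 28.9%, where chance gives 0.433% if the 11 arrays count as separate samples. With consecutive wild-type arrays averaged, 1161 of 3164 rows with all 8 values, or 36.7%, did not overlap, where chance gives 3.57%. Most calls were small: their median absolute log2 fold change was 0.61, and 53 rows were higher and 121 lower by 2-fold or more. The split between directions depended on the scaling. On the deposited values 1814 rows were higher and 281 lower, with each array centred on its median 631 and 860, and after cyclic loess 716 and 651. Under all 4 scalings, 530 rows were called higher and 256 lower, of which 127 and 29 had 1 gene name.

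**Figure D2:**
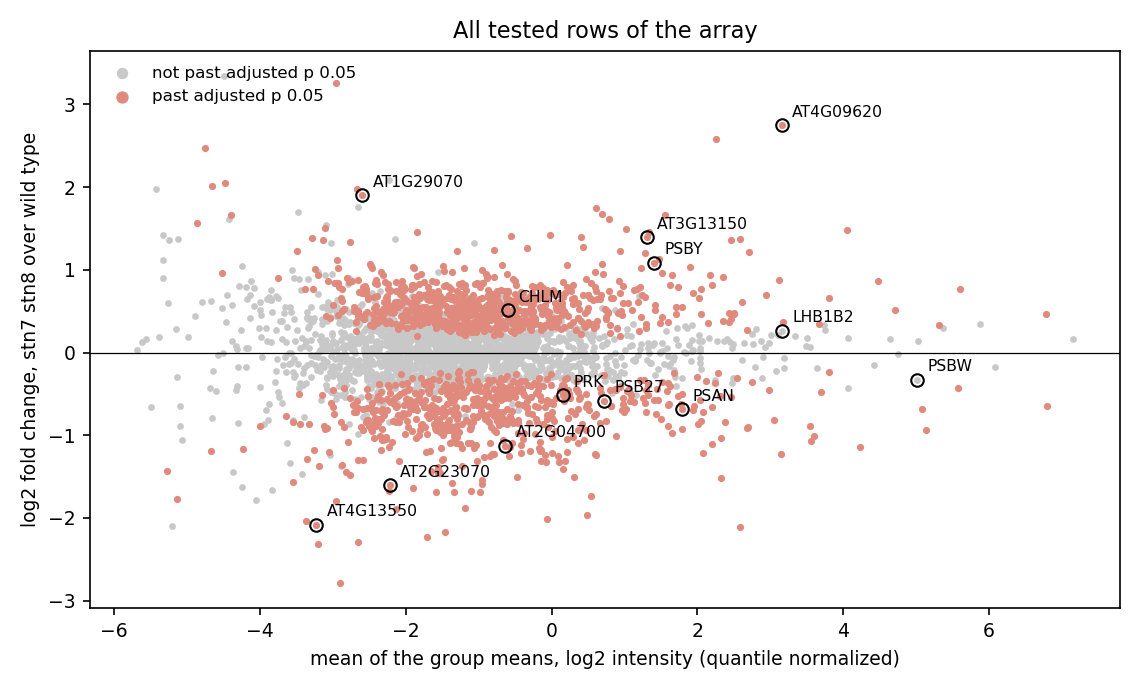
Log2 fold change (mutant over wild type) of each of the 3229 tested rows against the mean of the group means in log2 intensity, both quantile normalized; red points passed an adjusted p of 0.05 and circles mark genes named in the text. Called rows lay in both directions, with AT4G09620 the highest of the circled genes (2.75) and AT4G13550 the lowest (-2.08).

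Among rows with 1 gene name that kept their call when single arrays were left out, the largest increase was that of AT4G09620, from 1.79 ± 0.33 (log2, SD, n = 6) to 4.53 ± 0.46 (n = 5), a log2 fold change of 2.75 ± 0.22 (SE, adjusted p = 4.9e-06, limma). AT3G52550 followed with 1.98 ± 0.38 (adjusted p = 0.00161, limma) and AT1G32220 with 1.45 ± 0.16 (adjusted p = 5.1e-05, limma). The order depended on the scaling. On the deposited values AT3G52550 was at 2.59 and AT4G09620 at 2.43, and with arrays centred on their medians at 2.05 and 1.89. AT3G13150 rose by 1.39, AT1G01730 by 1.27, PSBY by 1.09, AT5G24690 by 1.05, AT4G18180 by 1.04 and AT5G17280 by 1.02 on the log2 scale. AT1G29070, the plastid ribosomal protein L34, was higher by 1.91 ± 0.60 (adjusted p = 0.0222, limma), but much of this came from 1 array: without mutant replicate 3 the log2 fold change was 1.24 (adjusted p = 0.00961, limma). With the median intensity added before the log2 step, its call was lost (0.68, adjusted p = 0.0909, limma; range over alternatives 0.00264 to 0.0909). It was also lost when consecutive arrays were averaged in both groups, averaged in wild type alone or set as a random block (adjusted p = 0.0832, 0.0833 and 0.0555, limma). Averaging in both groups left mutant replicate 3 alone as a unit, and the log2 fold change was 2.35 there. The call of AT5G17280 was lost with consecutive arrays as a random block (adjusted p = 0.0874, limma, range 2.9e-04 to 0.0874). Mutant replicate 1 was the highest array of AT5G17280, at 0.36, and the next lay at -0.66. Without that array its log2 fold change was 0.76, and the call held.

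The largest decrease among the same rows was that of AT4G13550, a plastid lipase, at -2.08 ± 0.39 on the log2 scale (adjusted p = 0.00134, limma). It was followed by AT2G23070, the alpha subunit of the plastid casein kinase 2, at -1.61 ± 0.12, from -1.41 ± 0.14 (n = 6) to -3.02 ± 0.25 (n = 5; adjusted p = 3.4e-06, limma). AT3G57630 fell by 1.25, AT3G26580 by 1.23, AT2G38550 by 1.22 and AT4G38020 by 1.17 on the log2 scale. AT2G04700 fell by 1.13, AT2G46630 by 1.12, AT4G22370 fell by 1.105 and AT4G00170 fell by 1.097. In all 20 genes of these 2 groups the values of the 5 mutant arrays lay outside the range of the 6 wild-type arrays. These genes were chosen from the same arrays by size and stable calls, which favours such a separation, so it adds no support. Their directions were the same under all 4 scalings, and all passed under each. Their sizes were not: 9 of them moved by over 1.5 times under at least 1 other scaling, such as AT4G18180 to 0.38 with arrays centred on their medians and AT4G38020 to -0.58 on the deposited values. With the median intensity added before the log2 step, which shrinks the changes of dim rows, AT4G13550 was at -0.45, AT2G23070 at -0.57, AT3G52550 at 0.54 and AT1G32220 at 0.58, and all 4 passed. The order changed there. AT4G13550, which lay at the 6.38 percentile of brightness, had a smaller decrease than every other decreased gene named here except AT4G38020 (-0.39). The lowest were AT3G26580 at -0.97, AT3G57630 at -0.90 and AT2G38550 at -0.87. Among the increases, AT3G13150 at 1.19 and PSBY at 0.93, with others, lay above AT3G52550.

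Few members of the 23 chloroplast and related gene lists could be measured. Rows with 1 gene name covered 19 members in 10 lists, of which 4 were higher, 5 lower and 10 did not pass. Adjusted over the list alone, 6 were higher and 7 lower. For a list with 1 measured member that p is unadjusted. The other 13 lists had 0 measured members. They were the STN kinases, partners of thylakoid phosphorylation and state transitions, the photosystem I antenna, photorespiration, carotenoid synthesis, LHC-like proteins of light stress, plastid proteases, plastid import and chaperones, plastid sigma factors and RNA polymerases, starch and sugar export, nitrogen and sulfur assimilation, jasmonate synthesis and defence, and plastid markers of non-green tissue. The last list was meant to show other tissues, so the tissue makeup of the samples was not tested here.

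Of 3 measured photosystem II subunits, 1 rose, 1 fell and 1 did not pass; adjusted over the list alone, 1 rose and 2 fell. PSBY rose from 0.86 ± 0.19 to 1.94 ± 0.17 on the log2 scale (SD, n = 6 and 5; adjusted p = 3.4e-05, limma), and PSB27 went from 1.01 ± 0.27 to 0.43 ± 0.15, a change of -0.58 ± 0.13 (SE, adjusted p = 0.00463, limma). PSBW, among the brightest rows of the array, had a log2 fold change of -0.33 (adjusted p = 0.0685, limma), and was called lower under the other scalings, at -0.90 on the deposited values, -1.44 with arrays centred on their medians and -0.42 after cyclic loess (adjusted p = 6.9e-05, 1.6e-05 and 0.0148, limma; range over alternatives 1.6e-05 to 0.272). Over the 4 scalings, PSBY ranged from 0.52 to 1.09 and PSB27 from -0.999 to -0.46, and both passed under each. As a set the list did not stand apart from other genes (camera, lower, adjusted p = 0.655; adjusted p = 0.673 with an estimated correlation), and its mean log2 fold change of 0.059 and its median of -0.33 differed in sign. PSAN, the 1 measured photosystem I subunit, changed by -0.69 ± 0.22 (adjusted p = 0.0248, limma) and lay below the wild-type mean in 4 of 5 mutant arrays. Its call was lost when single arrays were left out (adjusted p up to 0.0639, limma) and when consecutive arrays were averaged (0.0917, or 0.0967 in wild type alone), and with arrays centred on their medians it changed by -1.29. For LHB1B2 of the photosystem II antenna, whose row may also detect near-identical LHCB1 copies, the log2 fold change was 0.26 (adjusted p = 0.118, limma) and 0.072 on the deposited values, and it turned to -0.47 (adjusted p = 0.0268, limma) with arrays centred on their medians, while after cyclic loess it was called higher at 0.36 (adjusted p = 0.0327, limma; range over alternatives 0.0268 to 0.688). NdhN, a subunit of the chloroplast NDH complex, gave 0.24 (adjusted p = 0.0588, limma). It was higher adjusted over the list alone and in 6 of 28 alternatives, among them the deposited values at 0.74 (adjusted p = 2.9e-04, limma; range 2.9e-04 to 0.186).

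**Figure D3:**
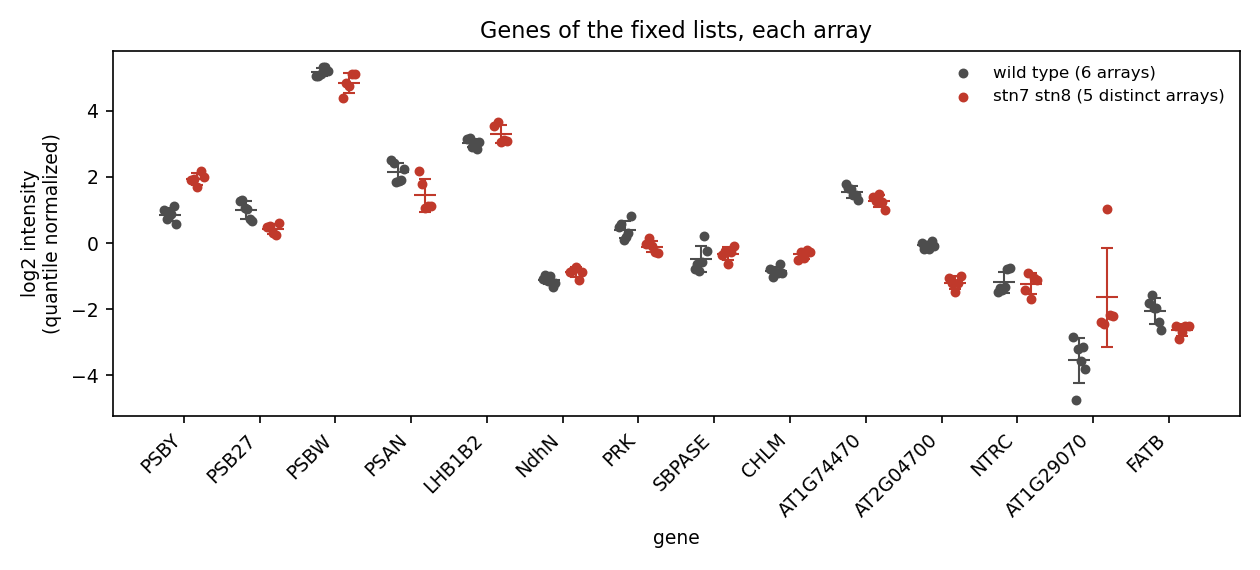
Quantile-normalized log2 intensity of 14 measured members of the gene lists in each wild-type array (grey, 6) and each distinct stn7 stn8 array (red, 5), with bars for mean and SD. PSBY and CHLM lay higher and PSB27 and AT2G04700 lower in every mutant array than in any wild-type array, while 1 mutant array of AT1G29070 lay at 1.02, above the other 4.

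In the Calvin cycle, 1 of 2 measured members fell: PRK changed by -0.52 ± 0.14 (SE, adjusted p = 0.0101, limma; -0.84 with arrays centred on their medians and -0.30 on the deposited values, where it did not pass, nor did it with consecutive arrays averaged, with adjusted p from 0.00143 to 0.0655 over 28 alternatives), and SBPASE, the sedoheptulose bisphosphatase, gave 0.16 (adjusted p = 0.510, limma). SBPASE was called higher on the deposited values at 0.50, with a block for the replicate number at 0.29 and without wild-type replicates 5 and 6 at 0.37 (adjusted p = 0.0282, 0.0269 and 0.0260, limma, range over alternatives 0.0260 to 0.889). With arrays centred on their medians it gave -0.042. In chlorophyll synthesis, CHLM was higher by 0.51 ± 0.093 (adjusted p = 0.00104, limma), with all mutant arrays above all wild-type arrays. It was at 0.91 on the deposited values, 0.37 with arrays centred on their medians and 0.31 with the median intensity added before the log2 step, and passed in all 28 alternatives. The geranylgeranyl reductase AT1G74470 gave -0.27 (adjusted p = 0.0807, limma). AT1G74470 was lower adjusted over the list alone and in 10 of 28 alternatives, among them arrays centred on their medians at -0.81 (adjusted p = 1.8e-04, limma; range 1.8e-04 to 0.319). Of 2 members of the plastid thioredoxin system, AT2G04700 fell from -0.070 ± 0.090 to -1.20 ± 0.19 (adjusted p = 8.7e-06, limma). Its log2 fold change was smaller on the deposited values, at -0.72, and with the median intensity added before the log2 step, at -0.69. It passed in all 28 alternatives. NTRC, the thioredoxin reductase fused to its thioredoxin, gave -0.053 (adjusted p = 0.837, limma) but was called higher on the deposited values at 0.47 (adjusted p = 0.0210, limma; range over alternatives 0.0210 to 0.988). The peroxiredoxin AT3G52960, the 1 measured plastid antioxidant enzyme, gave -0.15 (adjusted p = 0.311, limma) and 0.095 on the deposited values. It was called lower with arrays centred on their medians at -0.44 and without mutant replicates 1 and 2 at -0.33 (adjusted p = 0.00741 and 0.0315, limma; range over alternatives 0.00741 to 0.689). FATB, the thioesterase that releases saturated fatty acids in the plastid, changed by -0.57 ± 0.17 (adjusted p = 0.0190, limma), but by 0.028 on the deposited values, where it did not pass (adjusted p from 6.6e-04 to 0.917 over alternatives). It was at -0.20 with the median intensity added before the log2 step, where it passed. It passed in 22 of 27 alternatives, and its call was also lost with consecutive arrays averaged or as a random block and without mutant replicates 1 and 2 (adjusted p = 0.0848, 0.0523 and 0.0735, limma).

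Of 5 measured plastid ribosomal proteins, 2 rose and 3 did not pass; adjusted over the list alone, 3 rose. Besides AT1G29070 these were AT3G13120 (protein S10), higher by 0.37 ± 0.14 (adjusted p = 0.0492, limma), whose call was lost when single arrays were left out (adjusted p up to 0.0946, limma) and held in 10 of 28 alternatives, and, over the list alone, AT3G54210 (protein L17) at 0.29. On the deposited values AT3G13120 was at 0.95 and AT3G54210 at 0.63, and both passed. With arrays centred on their medians AT3G54210 was at 0.088 (adjusted p = 0.527, limma; range over alternatives 0.00169 to 0.527). AT3G13120 was at 0.15 with the median intensity added before the log2 step, and did not pass. AT1G64510 (protein S6) gave 0.24, and was called higher on the deposited values at 0.83 (adjusted p = 0.00555, limma). AT4G01310 (protein L5) gave -0.19, or 0.17 on the deposited values, and was called lower with arrays centred on their medians at -0.37 (adjusted p = 0.0119, limma). The list did not stand apart from other genes (camera, higher, adjusted p = 0.655; adjusted p = 0.673 with an estimated correlation).

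When arrays with consecutive numbers, which resembled each other in wild type, were averaged to 3 against 3, limma called 416 rows higher and 387 lower. With only the wild-type arrays averaged, 3 against 5, the counts were 542 and 468. Without wild-type replicates 5 and 6, which stood apart from the other wild-type arrays, the counts were 800 and 685, and without mutant replicates 1 and 2 they were 699 and 562.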

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

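The arrays below were set apart by a test fixed beforehand, and the rows listed at 0 were counted after the data were seen. In 102 groups of values, of the named genes and the array measures, 3 had 1 array far from the others, where chance gives about 1 in 20 groups. For AT1G29070, the plastid ribosomal protein L34, mutant replicate 3 had a normalized log2 intensity of 1.02, and the other 4 mutant arrays lay between -2.46 and -2.18. Leaving that array out moved its log2 fold change from 1.91 to 1.24. For AT4G22370, wild-type replicate 4 was at -1.20 and the other wild-type arrays between -0.71 and -0.50. For AT4G00170, mutant replicate 6 was at -1.81 and the other mutant arrays between -1.62 and -1.60. Both genes kept their calls without these arrays.

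Among the rows left out of the test for too few values, 3 were above 0 in every mutant array and listed at 0 in every wild-type array. They were AT4G22830, AT2G11270 and 1 row without a gene name. In the other direction there were 0 such rows. No fold change is given, because an entry of 0 has no stated meaning in the table.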

How the results depend on the processing

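The averaged and blocked pairs, the doubled identical arrays, the arrays left out together and the test of same-numbered arrays were chosen after the results were seen. Of 35 genes past the threshold that were named by the rules, 20 kept call and direction in all settings with a value. So did 18 of the 20 named by size, while AT1G29070 and AT5G17280 did not. LPA19 and SPL, also past the threshold but named only to complete a list, are not among the 35. On the deposited values 1814 rows were higher and 281 lower. There NTRC turned to 0.47, FATB to 0.028, CRR41 to 0.055 and PIFI to 0.23 (log2). The photosystem II list passed camera there (lower, adjusted p = 0.0363, range over alternatives 0.0363 to 0.772). Its measured members lay at brightness percentiles of 90.9 to 99.7, and deposited fold changes were lowest in bright rows. This pass therefore cannot be told apart from brightness. With arrays centred on their medians LHB1B2 turned to -0.47. The median log2 fold change of 0.50 over tested rows was seen in the deposited values, before any scaling between arrays. It was not uniform, at 0.68 in the dimmest of 10 brightness classes and -0.084 in the brightest. Its possible causes are taken up under the other observations, where saturation and a flatter transcript profile stay open. An adjusted p under 0.01 left 507 higher, and a fold of at least 1.5 left 336 higher and 399 lower. The ribosomal list passed fry (adjusted p = 0.0044; range 0.0044 to 0.772), as did the assembly factor, redox and cell wall lists (0.00482, 0.00915 and 0.0183). Camera gave adjusted p = 0.673, 0.428, 0.520 and 0.520 for these 4 lists with an estimated correlation; fry does not compare a list with other genes. Averaging consecutive arrays, with fewer samples, gave 416 and 387, averaging them in wild type alone 542 and 468, and a random block for them 506 and 456. Leaving out single arrays gave 685 to 753 higher and 590 to 628 lower. All other counts stayed within 1.5 times the main ones. Same-numbered arrays deviated together on average, with the merged array as number 4 (mean r = 0.147, exact permutation p = 0.00278 over 720 assignments) or 5 (0.163, p = 0.00139, exact permutation). As number 5 all 5 mutant arrays correlated best with their own number, as number 4 all but the merged one. The r of the merged array was low, at 0.0905 or 0.0094. Both mean r were past the limit set for this test, so the numbers may mark a shared technical unit. No label states such a pairing, and the main fit has no block for it. With the replicate block the counts were 796 and 629, or 818 and 632 with the merged array as number 5, no list passed camera, SBPASE (0.29) and AT1G74470 (-0.28) were called and AT3G13120 (0.37) was lost (adjusted p = 0.0269, 0.0295 and 0.0751, limma). As number 5, NdhN, AT3G54210 and AT1G74470 were called (0.0277, 0.0452 and 0.0223) and AT3G13120 and FATB lost (0.0660 and 0.0785). No background or detection flags were used, so what the dimmest rows measure stays unknown; without the dimmest 25% of rows 677 were higher and 555 lower.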

Other observations

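The tests of other splits, of a constant background and of consecutive arrays were chosen after the results were seen, and the 5 lists here after the gene names on the array were seen. Of 11 measured factors for plastid gene expression and complex assembly, 1 was higher and 3 were lower in the mutant. CRR41, an assembly factor of the chloroplast NDH complex, changed by -0.46 ± 0.10 on the log2 scale (SE, adjusted p = 0.00445, limma) but gave 0.055 on the deposited values. LPA19, an assembly factor of photosystem II, changed by -0.44 (adjusted p = 0.0247, limma), or 0.022 on the deposited values. PIFI changed by -0.38 (adjusted p = 0.0182, limma), or 0.23 on the deposited values. Its call held in 21 of 27 alternatives (adjusted p from 0.00614 to 0.191) and was also lost with arrays centred on their medians, with consecutive arrays averaged in both groups, averaged in wild type alone or set as a random block, and without mutant replicates 1 and 2. CRR21, which acts in RNA editing of an NDH transcript, was higher by 0.41 ± 0.13 (adjusted p = 0.0198, limma). It was at 0.81 on the deposited values, and at 0.27 with arrays centred on their medians, where the call was lost (adjusted p = 0.103, limma; range over alternatives 7.0e-05 to 0.168). With the median intensity added before the log2 step CRR41 was at -0.25, PIFI at -0.13 and CRR21 at 0.25, and all 3 passed. The calls of LPA19 and CRR21 were lost when single arrays were left out (adjusted p up to 0.0574 and 0.0523, limma). CRR21 held in 23 and CRR41 in 26 of 28 alternatives. The list did not stand apart from other genes (camera, adjusted p = 0.183). Of 6 redox and antioxidant proteins, AT2G04700 alone passed. CCS gave 0.18, but was called higher on the deposited values at 0.80 and with arrays centred on their medians at 0.26 (adjusted p = 1.5e-04 and 0.0490, limma; range over alternatives 1.5e-04 to 0.556). GLDH gave -0.32, or 0.28 on the deposited values, and passed in none of its alternatives. The redox list did not stand apart from other genes (camera, adjusted p = 0.183). All 8 measured photosynthesis genes combined, of which 1 was higher and 3 lower, gave a camera adjusted p of 0.613, and 0.0183 (lower) on the deposited values. All 8 lay at or above the 58.3 percentile of brightness, so the latter cannot be told apart from the lower deposited fold changes of bright rows.

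Of 5 cell wall enzymes, 2 were higher and 1 lower. GH9B16, GH9B12 and GH9B8 belong to the endoglucanase-like glycosyl hydrolase family 9. GH9B16 fell by 0.99 on the log2 scale (adjusted p = 2.5e-04, limma), with all mutant arrays below all wild-type arrays, but did not pass on the deposited values (-0.40, adjusted p = 0.0981, limma). GH9B12 was higher by 0.42 and GH9B8 by 0.40 (adjusted p = 0.0376 and 0.0454, limma), and both calls were lost when single arrays were left out (adjusted p up to 0.0897 and 0.108, limma). They held in 11 and 9 of 27 alternatives. On the deposited values they were at 1.02 and 1.001 and passed (adjusted p = 1.0e-04 and 8.7e-04, limma; ranges over alternatives 1.0e-04 to 0.228 and 8.7e-04 to 0.182). With the median intensity added before the log2 step they were at 0.13 and 0.12 and did not pass, while GH9B16 was at -0.38 and passed. Of 5 reproductive regulators, 2 were higher and 2 lower: DME, a DNA demethylase, by 0.46 ± 0.12 and SPL by 0.28, against AGL103 at -0.57 ± 0.12 and AGL26 at -0.73 ± 0.18 (adjusted p = 0.00938, 0.0177, 0.00304 and 0.00652, limma). On the deposited values AGL103 and AGL26 did not pass (-0.096 and -0.16), while DME was at 1.02 and SPL at 0.84 and both passed. With the median intensity added before the log2 step DME was at 0.22, AGL103 at -0.32 and AGL26 at -0.31, and all 3 passed. DME lost its call when consecutive arrays were averaged or set as a random block (adjusted p = 0.0656 and 0.0663, limma; range over alternatives 7.1e-05 to 0.0663). Neither list stood apart from other genes (camera, adjusted p = 0.490 and 0.613). Called rows with 1 gene name were higher in 62.6% of cases and other called rows in 52.9% (Fisher's exact test, p = 0.00377). The test counts rows as independent, which they are not, and was run on the main scaling only. The directions of the named genes need not represent those of the whole array.

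The real grouping gave 1398 calls. Of 100 splits of the 11 arrays into 6 and 5, 1 gave as many, the real one, so a random grouping can be excluded as their source if the 11 arrays are separate samples. The highest other split gave 858. It and 1 other, with 645 calls, set 5 wild-type arrays against all mutant arrays and the remaining wild-type array. The other 97 gave at most 2 calls. With consecutive wild-type arrays averaged, 1 of the 56 splits of the 8 units into 3 and 5, again the real one, gave as many as its 1010 calls, and the highest other gave 1. With mutant arrays averaged too, 10 splits are too few for a share under 0.05. This excludes neither a shared technical difference between the groups nor a mutant effect, since no label parts the groups by batch.

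As deposited, the mutant arrays had medians higher by 0.54 and a narrower spread. A constant background in the mutant arrays would raise the dimmest rows most, and the values argue against it. The median fold change of the dimmest of 10 brightness classes exceeded that of class 5 by 0.14 ± 0.043 (bootstrap SE), where at least 0.5 was needed. The bootstrap drew rows with the arrays held fixed, so this SE leaves out the spread between arrays. A smaller share of the brightest 1% of rows in a common total also falls short as the whole cause. The totals without them differed by 0.20 on the log2 scale, against 0.54 for the medians. It may account for part, and a larger bright fraction was not tested. Saturation of bright spots stays open, because the correlation of fold change and brightness across the brightest 10% of rows (rho = -0.252) and the 72.7% of the brightest 33 rows that were lower lay between the limits set for either answer. A flatter profile of transcript levels in the mutant stays open too and was not tested apart from labelling or exposure.

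Wild-type arrays with consecutive numbers deviated together from the group mean (mean r = 0.448 over 3 pairs; highest of the other 14 ways to pair them, 0.260). They may share an extract or a filter. The mutant arrays leave this open, since replicates 1 and 2 had r = -0.37 and the merged array and replicate 6 had r = 0.21. As number 4 the merged array would pair with replicate 3, at r = -0.26. If the wild-type pairs are repeat arrays, wild type has 3 independent samples, and averaging those pairs alone left 542 rows higher and 468 lower. The counts of 416 and 387 also average mutant arrays, for which the correlations show no such pairing throughout.

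A hypothesis was that genes beside the 2 targeted loci, carried along with the insertions, hold part of the calls. Of the 20 named and measured genes nearest to each locus, 9 were called for STN7 and 7 for STN8, together 16. Of random pairs of such windows along the genome, a share of 0.684 had as many, so the windows held no excess of calls. Named and measured genes are sparse, so many of the 20 need not flank the locus. Of tested rows with 1 gene name, 43.1% were called. An effect on a few flanking genes could not be seen in this way.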
